A study of Homo sapiens with 5 samples.

How the data were processed

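Cells labelled HepG2, a human liver cancer line, were profiled on 5 Agilent whole-genome arrays of 44495 spots each, 1 array per group: control (RetroQ vector) and shRNA against EZH2, SUZ12, BMI1 or CBX8. Groups were taken from the treatment labels. Intensity values are Cy3 processed signals of each spot, which per the file headers Agilent Feature Extraction 10.7.3.1 made by subtracting the local background in a 1-colour protocol; other columns used were the deposited flags for spots well above background, outliers and saturation, the spot error, and the median signals of spot and local background. The submitters' processing notes name Feature Extraction 9.1, which differs from the headers. The labels' extraction text speaks of Cy5 and Cy3 samples hybridised together, whereas the labelling text and the files hold Cy3 only, so the arrays were read as 1-colour. That text also names a luciferase hairpin among the cells, and the control's own labels name the RetroQ vector. No aligner or genome build enters these values.

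Symbols came from the RefSeq accession of each probe, matched without versions to a table of the GRCh38.p14 assembly, which was used for names only; 25505 of 34127 probes had a symbol, for 19542 genes, and 8622 had none. Processed signals were put on the log2 scale and the array's 75th percentile over non-control spots was subtracted. Control spots and outlier spots (0.70% to 1.75% per array) were left out; no spot was saturated. Spots of a probe were averaged, a probe was measured where at least a share of 0.5 of its spots was well above background, and a gene took its probe with the highest mean over the 5 arrays. Of genes with more than 1 measured probe, the next probe lay on the other side of the median difference for 34.6%, 36.7%, 41.1% and 40.5% on the EZH2-, SUZ12-, BMI1- and CBX8-labelled arrays. Correlations between these probes across genes were 0.37, 0.33, 0.26 and 0.25. Where the first probe lay at least 2-fold from that median, the next did so the same way for 36.8%, 32.4%, 27.5% and 34.8%. Pairing at random would give 22.4%, 19.3%, 14.0% and 17.8%. Probes measured numbered 17284, 20951, 19532, 11803 and 8906 on the control, EZH2-, SUZ12-, BMI1- and CBX8-labelled arrays, and the SD of log2 signal among replicate spots of a probe was 0.15, 0.10, 0.11, 0.17 and 0.19, which is technical. The number of arrays, 1 per group, limits the precision.

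The deposited series table was matched to the spots by feature number and held the processed signals rounded, with a largest deviation of 0.497%, neither log-transformed nor scaled or centred; its column medians were 12.1, 27.5, 27.0, 6.42 and 7.55 in the order above. The control, EZH2-, SUZ12- and CBX8-labelled arrays shared 1 scan date in the file headers, taken here as slide 1. The BMI1-labelled array had another scan date, taken as slide 2, and no slide identifier was read. The comparison for BMI1 thus could not be made within a scan date, and the others already were.

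With 1 array per group no test was run and no p-value given. The comparisons, the size rule of 2-fold (log2 of 1), the gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. The rule chose the genes to name from, for each comparison, the 4 targeted genes, the 12 genes with the highest and the 12 with the lowest difference among genes with a symbol measured on both arrays, the 3 with the largest bound each way, and up to 4 members of each list with the largest absolute difference; for overlaps it took the 10 at each end. Genes measured on 1 of 2 arrays were given a bound, the bright value over the higher of the lowest measured signal and the dim probe's own on the other array. The 36 lists held 860 different genes, of which 840 were on the array; a list needed at least 5 measured members. Each median was placed among 10000 random lists matched on 10 bins of mean expression, and lists outside the central 95% were called. Simulated unchanged arrays used the spot error and 100 draws. Cultures, passages and hairpin sequences are not given in the sources used here.

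The calculation was tested on simulated data for the real genes: with 11083, 10889, 7677 and 5445 genes for the EZH2, SUZ12, BMI1 and CBX8 comparisons, 100% of genes changed 4-fold and 100% of those changed 8-fold were recovered, and 8 of 10883, 8 of 10689, 4 of 7477 and 1 of 5245 unchanged genes were called. These simulated arrays held the control values plus the spot error only, with every gene taken as measured. Recovery of changes larger than the size rule was thus largely fixed by construction. The few false calls check the calculation and give no error rate for the real arrays, which also differ in brightness and between probes of a gene. Of random lists 3%, 3.5%, 5.5% and 4% were called, and of lists shifted by 1 log2 unit 45%, 65%, 100% and 100%.

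Alternatives were quantile normalization, cyclic loess, the median in place of the 75th percentile, normexp background correction with an offset of 50 followed by quantile normalization, the series table, the mean over probes, genes measured on all 5 arrays, no filter on dim probes, bounds for genes measured on 1 array, a 3-fold rule, an added requirement of 2 times the spot error, unmatched random lists, and arrays of slide 1 only. Normexp used the median spot signal, since the files hold no mean signal. Alternatives chosen after seeing the data were no scaling, centring on the median difference, the 75th percentile over probes measured on all 5 arrays, leaving out spots whose local background exceeded 2 times the array's median (8, 0, 15, 128 and 16 spots in the order above), and leaving out each knockdown array in the comparison of complexes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used. XIST and genes of the Y chromosome were left out of tables and plots by gene.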

Results

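Polycomb repressive complexes keep developmental genes silent through marks on histones. EZH2 is the enzyme of Polycomb repressive complex 2 (PRC2) that methylates histone H3 at lysine 27, and SUZ12 is a core subunit of the same complex, whereas BMI1 and CBX8 belong to Polycomb repressive complex 1 (PRC1). RNA was measured on 5 arrays of cells labelled HepG2, a line from a human liver cancer: 1 array of cells with the empty RetroQ vector, the control, and 1 array each of cells with a short hairpin RNA (shRNA) against EZH2, SUZ12, BMI1 or CBX8. Each group held 1 array, so there were no replicates, no difference could be tested, and every value describes these arrays only. Differences are in log2 units, knockdown-labelled array minus control array, and the error after ± is the scanner's spot error of both arrays, which leaves out the spread between cultures. A gene was called higher or lower at a log2 difference of at least 1, that is 2-fold.

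The arrays differed in brightness before scaling. The 75th percentile of processed signal was 58.8 intensity units on the control array, 154 on the array labelled EZH2-shRNA, 147 on that labelled SUZ12-shRNA, 26.2 on that labelled BMI1-shRNA and 35.6 on that labelled CBX8-shRNA, a ratio of 5.89 between the brightest and the dimmest. Genes well above background numbered 11299, 13595, 12873, 7788 and 5899 of 19542 in that order, and 5111 genes were measured on all 5 arrays.

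**Figure D1:**
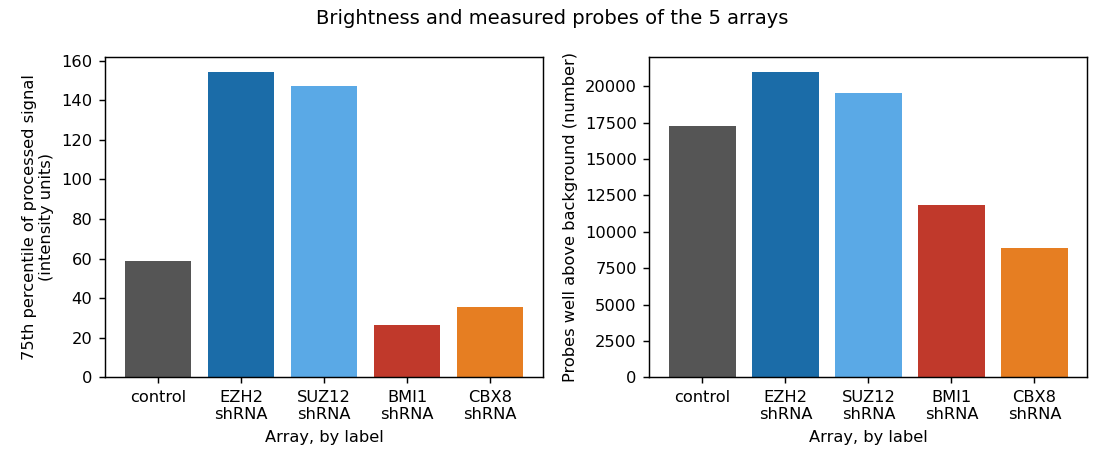
The 75th percentile of processed signal (left, intensity units) and the number of probes well above background (right) on each of the 5 arrays, 1 bar per array. The arrays labelled EZH2-shRNA and SUZ12-shRNA were brighter than the control array (154 and 147 against 58.8) and those labelled BMI1-shRNA and CBX8-shRNA were dimmer (26.2 and 35.6), and probes above background ranged from 8906 to 20951.

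The transcripts targeted by the hairpins came first, since they check the labels. The EZH2 probe was not well above background on the control array and was measured on the array labelled EZH2-shRNA, at least 1.37-fold higher, and on the array labelled SUZ12-shRNA, at least 2.39-fold higher. EZH2 was thus not seen to be lower on its own array. Its difference there, 2.10 ± 1.45, rested on 1 probe at background on the control array, and its bound was under 2-fold. This does not show that a label is wrong, and all directions below hold for the arrays as labelled. SUZ12 differed by -0.39 ± 0.30 on the array labelled SUZ12-shRNA and by -0.42 ± 0.29 on the array labelled EZH2-shRNA, while the median gene differed by -0.31 and -0.40 on these arrays. Neither BMI1 probe was well above background on the control array or the array labelled BMI1-shRNA, and 1 of them was measured on the arrays labelled EZH2-shRNA, with no bound over 1, and SUZ12-shRNA, at least 1.54-fold higher. CBX8 was not well above background on the control array or the array labelled CBX8-shRNA and was at least 2.21-fold higher on the array labelled EZH2-shRNA and at least 1.85-fold higher on that labelled SUZ12-shRNA. The difference of CBX8 on its own array, 2.19 ± 0.72, pointed upward but rested on 1 probe that was not well above background on either array. SUZ12 did not pass the size rule for a decrease on its own array. EZH2, BMI1 and CBX8 were not measured on the control array, so no decrease from it could be called for them. Of the other PRC2 subunits, the histone chaperone RBBP7 rose on the arrays labelled EZH2-shRNA (2.02 ± 0.20) and SUZ12-shRNA (2.15 ± 0.20) and fell on those labelled BMI1-shRNA (-1.19 ± 0.21) and CBX8-shRNA (-1.50 ± 0.24). Among PRC1 subunits PHC3 rose by 2.88 ± 0.26 and 2.87 ± 0.26 on the first pair of arrays, where CBX7 fell (-1.54 ± 0.20 and -1.69 ± 0.20).

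The comparison of the array labelled EZH2-shRNA with the control array asked which transcripts depend on the PRC2 enzyme. Heat shock proteins, the chaperones that fold and refold other proteins, stood highest, with HSPB1 up by 2.85 ± 0.21, HSP90AB1 by 2.81 ± 0.21 and HSPA8 by 2.58 ± 0.21. Genes of mitosis and DNA synthesis were higher too, among them the cell cycle kinase CDK1 (3.02 ± 0.22), the spindle checkpoint kinase BUB1B (2.64 ± 0.22), the ribonucleotide reductase subunit RRM1 (2.76 ± 0.20) and the replication clamp PCNA (2.62 ± 0.23). The other measured probe of HSPB1 and that of PCNA differed downward, on this array and on the array labelled SUZ12-shRNA. Liver proteins and developmental regulators were lower, among them the protease inhibitor SERPINA1 (-1.76 ± 0.20), the bile acid receptor NR1H4 (-1.56 ± 0.21), coagulation factor F11 (-2.12 ± 0.23) and the transcription factor GATA4 (-1.96 ± 0.21). On the array surface GATA4 lay beside GOLGA6A, which differed by -3.03 here. In all, 2384 genes were higher and 3306 lower of 11083 measured on both arrays, 41.9% of the calls being higher. The median gene stood at -0.40, and after centring on it 3164 genes were higher and 1482 lower, 68.1% higher.

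Lists of genes fixed before the data were examined were placed among 10000 random lists of matched expression, and a list was said to rise or fall outside the central 95% of them. A list's median runs over members measured on at least 1 of the 2 arrays, and counts of members run over those measured on both. Values marked relative are the median minus that of the matched lists. On the array labelled EZH2-shRNA the heat shock list had a median of 1.86 (relative 2.05, percentile 100). Of 12 members 9 were higher and 1 lower. Mitochondrial oxidative phosphorylation rose by 1.39 (relative 1.61, percentile 100), with 15 of 27 members higher, among them COX6C (3.08 ± 0.21) and NDUFB3 (2.80 ± 0.21). Cytosolic ribosomal proteins rose by 1.06 (relative 1.42, percentile 100). Of 39 members 21 were higher and none lower; RPS23 was up by 3.04 ± 0.20. Proliferation and mitosis rose by 1.34 (relative 1.59, percentile 100). Of 29 members 16 were higher. DNA replication rose by 1.17 (relative 1.43, percentile 99.99). Of 24 members 14 were higher. The histone demethylases and trithorax group, which counter Polycomb repression, rose by 1.35 (relative 1.45, percentile 98.5); 5 of 8 members were higher, led by the histone methyltransferase KMT2D (2.29 ± 0.27) and the scaffold WDR5 (1.75 ± 0.27). Metallothioneins, small metal-binding proteins, rose by 0.89 (relative 1.23, percentile 98.4), with MT1M up by 2.46 ± 0.20, and targets of the oxidative stress regulator NRF2 by 0.92 (relative 1.13, percentile 98.7), with the ferritin chain FTH1 up by 2.78 ± 0.20. Reference genes often used to scale other transcripts also rose, by 0.68 (relative 1.00, percentile 97.55), led by the transferrin receptor TFRC (2.73 ± 0.20).

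Plasma proteins secreted by hepatocytes fell to a median of -1.16 (relative -1.08, percentile 0.41). Of 12 members 8 were lower and none higher, among them A1BG (-1.69 ± 0.20) and vitronectin, VTN (-1.43 ± 0.21). Complement and coagulation factors fell to a median of -1.01 (relative -0.82, percentile 0.68). Of 15 members 7 were lower. Liver-enriched transcription factors fell to a median of -1.01 (relative -0.83, percentile 1.89), with 7 of 11 lower, including FOXA3 (-1.31 ± 0.21). Developmental transcription factors outside the HOX clusters, classic Polycomb targets, fell to a median of -0.90 (relative -0.73, percentile 0.02). Of 43 members 26 were lower and 1 higher; MSX2 stood at -1.70 ± 0.20 and HAND2 at -1.67 ± 0.21. Markers of other cell types also stood low, without a call (neuronal genes -1.05, immune cell markers -0.97, stellate, fibroblast and endothelial markers -0.84). Before scaling, members measured on all 5 arrays differed by a median of 0.28 for developmental factors and 0.18 for plasma proteins on this array, and by 0.40 and -0.17 on that labelled SUZ12-shRNA. The largest single increases were those of the mitochondrial import chaperone TIMM10 (3.98 ± 0.29), the ribosome assembly factor WDR75 (3.93 ± 0.27), the small nucleolar RNA host gene SNHG6 (3.85 ± 0.21), the phospholipase PLAAT3 (3.73 ± 0.21) and the spliceosome protein SNRPD3 (3.70 ± 0.23), followed by TOP1MT, PUSL1, VASN, MAL2, TRIP6, GDI2 and CYB5D1 down to 3.41 ± 0.27. The largest decreases were those of the sarcoglycan SGCE (-3.81 ± 0.28), FAM200A (-3.68 ± 0.30), the transcription factor PRDM16 (-3.46 ± 0.23), DMBT1 (-3.36 ± 0.28) and HMGB3 (-3.35 ± 0.23), followed by the telomere protein POT1, CHST15, ENTREP1, TMEM82, OR1S1, ZNF761 and PCOLCE2 up to -3.03 ± 0.22. With the mean over all of its probes HMGB3 stood at 0.02. Of the 14 genes at least 8-fold lower, 3 had another such gene within 5 rows and 2 columns on the array surface: DMBT1, ZNF761 and PCOLCE2. That is 21.4%, against a mean of 1.43% and a highest value of 28.6% in 100 random draws. Of genes measured on 1 of the 2 arrays only, SAMD3, TUBE1 and CUTC were at least 33.8-, 22.2- and 21.2-fold higher on the array labelled EZH2-shRNA, and KLRD1, GNAI3 and SPATA19 at least 67.0-, 59.4- and 49.2-fold lower. All of these but GNAI3 had spots in rows 528 to 532 of the array surface, and their positions were not tested. The counts depended on the scaling: with none 5531 genes were higher and 51 lower. The 3306 genes lower after scaling differed by a median of 0.04 before it (quartiles -0.17 and 0.21). With normexp and quantile normalization the counts were 596 and 527, where the offset of 50 shrinks differences of dim genes by construction. List calls ended when only genes measured on all 5 arrays were used (developmental factors, DNA replication, plasma proteins, liver factors, NRF2 targets), with normexp (liver factors), with the mean over probes (metallothioneins), with unmatched random lists (metallothioneins, NRF2 targets, reference genes) or without the background filter (reference genes).

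The array labelled SUZ12-shRNA, the comparison for the PRC2 core subunit, showed a similar set of changes. CDK1 (3.001 ± 0.22), RRM1 (2.74 ± 0.20), the thymidylate synthase TYMS (2.66 ± 0.21), HSPB1 (2.65 ± 0.21), RPS23 (2.88 ± 0.20) and COX6C (3.01 ± 0.21) were higher. GATA4 (-2.91 ± 0.24), the transcription factor RUNX1 (-1.82 ± 0.21), the plasma glycoprotein AHSG (-1.53 ± 0.21) and SERPINA1 (-1.52 ± 0.20) were lower. The spot of GATA4 lay beside that of GOLGA6A, which was over 8-fold lower on this array. The endoplasmic reticulum chaperone HSPA5 (2.02 ± 0.22) and the amino acid stress genes ASNS (2.40 ± 0.21) and ATF4 (1.98 ± 0.20) were also higher. Of 10889 genes measured on both arrays 2275 were higher and 2604 lower, 46.6% of the calls being higher. The median gene stood at -0.31, and after centring on it 2870 were higher and 1271 lower, 69.3% higher.

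On this array the heat shock list rose by 1.80 (relative 2.06, percentile 99.97). Of 12 members 9 were higher. Oxidative phosphorylation rose by 1.19 (relative 1.44, percentile 100). Of 27 members 15 were higher and none lower. Cytosolic ribosomal proteins rose by 0.91 (relative 1.36, percentile 100). Of 39 members 19 were higher and none lower. Proliferation and mitosis rose by 1.16 (relative 1.42, percentile 99.99). Of 29 members 18 were higher. DNA replication rose by 1.18 (relative 1.43, percentile 100). Of 24 members 15 were higher. The histone demethylases and trithorax group rose by 1.31 (relative 1.48, percentile 98.5), with KMT2D up by 2.28 ± 0.27, and metallothioneins by 0.99 (relative 1.36, percentile 99.2), with MT1M up by 2.54 ± 0.20. The unfolded protein response, the program that answers misfolded protein in the endoplasmic reticulum, rose by 0.66 (relative 0.89, percentile 98.9). Of 23 members 9 were higher. Reference genes rose by 0.68 (relative 1.02, percentile 98.3), with TFRC up by 2.92 ± 0.20. Developmental transcription factors fell to a median of -0.79 (relative -0.67, percentile 0.07). Of 41 members 18 were lower. Hepatocyte plasma proteins fell to a median of -0.96 (relative -0.89, percentile 1.35). Of 12 members 6 were lower. NRF2 targets (0.64, percentile 95.8), liver-enriched transcription factors (-0.67, percentile 8.56) and complement and coagulation (-0.69, percentile 6.13), which were called on the array labelled EZH2-shRNA, were not called here, and the difference between the arrays was not tested.

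The largest increases were those of SNHG6 (3.91 ± 0.21), WDR75 (3.72 ± 0.27), PUSL1 (3.55 ± 0.28) and TIMM10 (3.54 ± 0.29), followed by PLAAT3, SNRPD3, VASN, TOP1MT, the Elongator subunit ELP2, CHCHD1, MCUR1 and FAM20B down to 3.34 ± 0.22. The largest decreases were those of the interferon-induced antiviral enzyme OAS2 (-3.90 ± 0.21), GOLGA6A (-3.51 ± 0.34), the leukocyte receptor LILRA1 (-3.44 ± 0.21) and GPX5 (-3.38 ± 0.21), followed by NEURL1B, OR1S1, SGCE, GP1BB, the potassium channel KCNN2, the transcription factor FOXO3, the polycystin PKD1 and TBATA up to -3.23 ± 0.21. Of the 31 genes at least 8-fold lower, 13 had another such gene within 5 rows and 2 columns on the array surface (41.9%, against a mean of 3.55% in 100 random draws), and 6 of the 12 named decreases were among them. Both other measured probes of OAS2 also differed downward, while no other measured probe of FOXO3 (2) or NEURL1B (1) did. Of genes measured on 1 of the 2 arrays only, MRPS9, CGA and RYK were at least 15.9-, 15.4- and 11.6-fold higher on the array labelled SUZ12-shRNA, and KLRD1, GNAI3 and SPATA19 at least 51.6-, 45.7- and 37.9-fold lower. The last 3 were also named on the array labelled EZH2-shRNA against the same control array. KLRD1 and SPATA19 had spots in rows 531 and 532, and these positions were not tested. With no scaling 5479 genes were higher and 120 lower, with normexp and quantile normalization 590 and 470, and the 2604 genes lower after scaling differed by a median of 0.02 before it (quartiles -0.19 and 0.17). List calls ended for the trithorax group (normexp, mean over probes, no background filter), developmental factors (genes on all 5 arrays, no background filter), DNA replication (genes on all 5 arrays), and the unfolded protein response, metallothioneins and reference genes (unmatched random lists).

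The array labelled BMI1-shRNA, the comparison for a PRC1 subunit, moved the other way. Ribosomal proteins fell, among them RPL27 (-3.25 ± 0.20), RPL4 (-2.23 ± 0.20) and RPLP0 (-2.16 ± 0.20), as did the glycolytic enzymes GAPDH (-2.58 ± 0.20) and GPI (-1.83 ± 0.21) and the replication factors RFC4 (-1.91 ± 0.22) and MCM2 (-1.67 ± 0.27). The death receptor TNFRSF10B was among the lowest (-3.52 ± 0.34). The complement protease MASP1 (1.497 ± 0.30), the anticoagulant PROS1 (1.49 ± 0.27) and the transcription factors FOXC1 (1.25 ± 0.20) and PAX9 (1.16 ± 0.20) were higher. Of 7677 genes measured on both arrays 835 were higher and 949 lower, 46.8% of the calls being higher. The median gene stood at 0.24, and after centring on it 404 were higher and 1287 lower, 23.9% higher.

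On this array cytosolic ribosomal proteins fell to a median of -1.10 (relative -1.09, percentile 0). Of 39 members 21 were lower and none higher. Hypoxia and glycolysis fell to a median of -0.93 (relative -0.95, percentile 0.145). Of 16 members 7 were lower and 1 higher. Metallothioneins fell to a median of -0.95 (relative -0.93, percentile 1.98), with 5 of 10 lower, among them MT1H (-1.38 ± 0.20). Proliferation and mitosis fell to a median of -0.72 (relative -0.74, percentile 0.22), with 3 of 18 lower, among them the survivin gene BIRC5 (-1.77 ± 0.21), and 2 higher. DNA replication fell to a median of -0.63 (relative -0.61, percentile 1.65). Of 18 members 9 were lower. Developmental transcription factors rose by 0.47 (relative 0.37, percentile 99.3). Of 30 members 6 were higher and none lower. Complement and coagulation rose by 0.60 (relative 0.46, percentile 98.3). Of 12 members 4 were higher. Hepatocyte plasma proteins rose by 0.67 (relative 0.63, percentile 98.8). Of 10 members 4 were higher. Of these plasma proteins, KNG1 and AHSG lay on spots whose local background was over 2 times the array's median, and the list was no longer called once such spots were left out. Before scaling, members measured on all 5 arrays differed by a median of -0.46 for developmental factors and -0.60 for plasma proteins. Markers of other cell types also stood high on this array, without a call. Lists called on another array and not here were heat shock proteins (-0.42, percentile 16.3), oxidative phosphorylation (-0.45, percentile 5.83), the trithorax group (-0.79, percentile 2.88), reference genes (-0.70, percentile 4.08), NRF2 targets (-0.52, percentile 4.97), the unfolded protein response (-0.43, percentile 5.92), Wnt targets (-0.69, percentile 6.36), mesenchymal markers (0.22, percentile 69.8), xenobiotic metabolism (0.46, percentile 91.8) and liver-enriched transcription factors (0.37, percentile 83.7).

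The largest increases on the array labelled BMI1-shRNA lay on raised local background: KNG1, the kinin precursor (12.34 ± 0.22), RGS6 (8.96 ± 0.33), CMBL (8.56 ± 0.32), KRTAP2-2, ANP32A, CD40LG, PLCD4, ZNF691, MITF, USP5, PPP2R2C and LBX2 (7.64 ± 0.24) all did. Of the 48 genes at least 8-fold higher, 37 lay on such spots and 40 had another within 5 rows and 2 columns (83.3%, against a mean of 6.06% in random draws). With these spots left out, a choice made after seeing the values, the same rule named JOSD2 (5.30 ± 0.33), the chromatin factor ADNP (4.62 ± 0.22), the ubiquitin ligase RNF25 (4.41 ± 0.22), EOLA2 (4.33 ± 0.26), hemopexin, HPX (3.80 ± 0.25), and ARHGEF10L (3.76 ± 0.34) first. JOSD2 and ADNP still lay beside other genes at least 8-fold higher, in the same patch of the array surface. The largest decreases were those of C11orf86 (-5.21 ± 0.35), TNFRSF10B, the thioredoxin-like TXNL1 (-3.37 ± 0.33), the nuclear export factor CSE1L (-3.36 ± 0.21) and the respiratory subunit NDUFS8 (-3.29 ± 0.23), followed by IFNGR1, RPL27, RPS27L, H1-2, AKR1B1, RAB31 and WDR45 up to -3.13 ± 0.30. Of the 15 genes at least 8-fold lower, C11orf86 and WDR45 had each other as such a neighbour. That is 13.3%, against a mean of 2.07% and a highest value of 20% in random draws. Of genes measured on 1 of the 2 arrays only, PDCD2L, MYT1 and UHRF1 were at least 710-, 633- and 617-fold higher, all on raised local background, and HACD1, ELMOD2 and MRPL20 at least 16.4-, 13.5- and 10.8-fold lower. The spot of MRPL20 (row 494, column 73) lay beside those of WDR45 and C11orf86. C11orf86 was also at least 32.5-fold lower on the CBX8-labelled array. Bright spots on the shared control array could give such decreases, which was not tested. This array was the only one with its scan date, taken as its slide, so scan date, slide and knockdown cannot be told apart. With no scaling 60 genes were higher and 3545 lower, and with normexp and quantile normalization 98 and 358. The excess of decreases turned with cyclic loess (906 higher and 831 lower), the mean over probes (938 and 812), the 75th percentile over probes measured on all 5 arrays (1115 and 818) and no filter on dim probes (6333 and 2070). The 835 genes higher after scaling differed by a median of 0.06 before it. List calls ended with normexp (developmental factors, DNA replication, complement), with no background filter (these and plasma proteins), with genes on all 5 arrays (plasma proteins, proliferation), with the mean over probes (complement, metallothioneins), with genes at their bound (DNA replication, complement) and without spots on raised local background (plasma proteins).

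**Figure D2:**
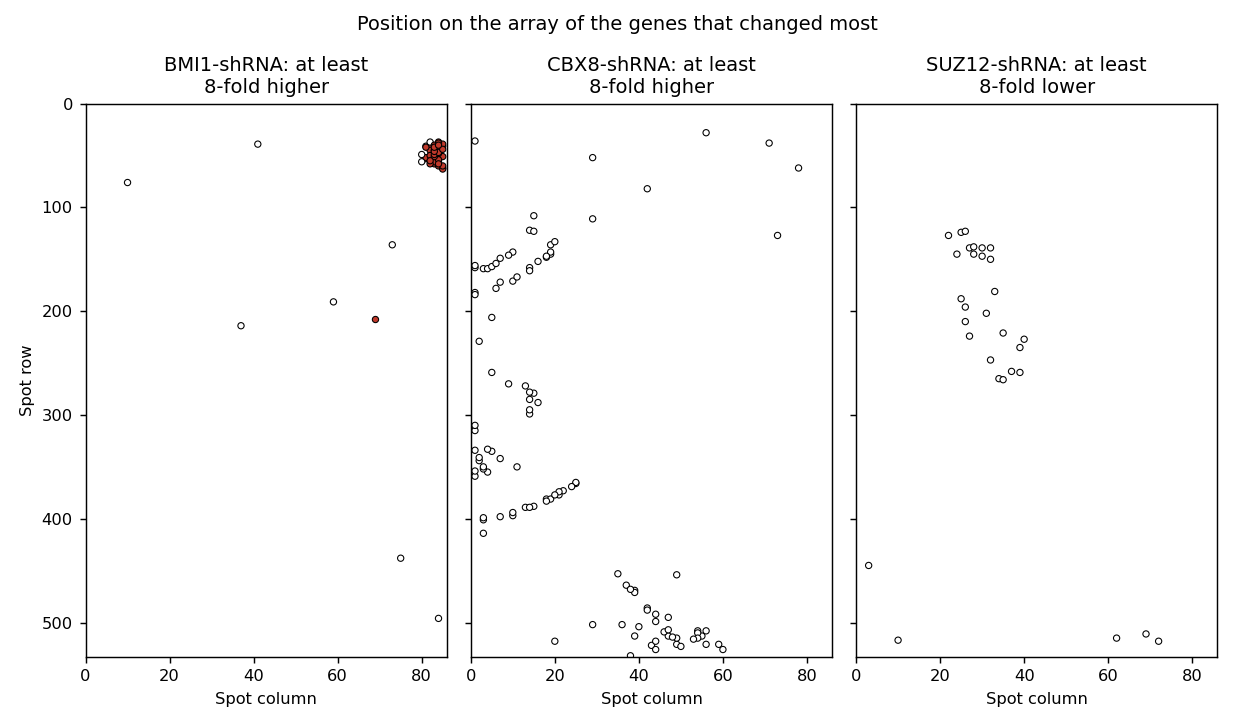
Row and column on the array surface of genes at least 8-fold higher on the array labelled BMI1-shRNA (left, 48 genes) and on that labelled CBX8-shRNA (middle, 115 genes), and of genes at least 8-fold lower on that labelled SUZ12-shRNA (right, 31 genes, of which a gene of the Y chromosome is not drawn); filled points lay on raised local background. In each panel many spots sit beside another: 83.3%, 72.2% and 41.9% had a neighbour within 5 rows and 2 columns.

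On the array labelled CBX8-shRNA, the comparison for the other PRC1 subunit, reference genes often used to scale other transcripts were lower. POLR2A, the largest subunit of RNA polymerase II (-2.60 ± 0.24), TFRC (-2.58 ± 0.39) and GAPDH (-2.52 ± 0.20) fell, as did BIRC5 of the mitosis list (-2.48 ± 0.22), the secreted Wnt inhibitor DKK1 (-2.91 ± 0.27) and the oncogene MYC (-1.88 ± 0.21). The calcium-binding protein S100A4 (1.91 ± 0.20), the actin-binding protein TAGLN (1.35 ± 0.23) and the acetyltransferase NAT2 (1.89 ± 0.27) were higher, TAGLN on a spot beside a gene at least 8-fold higher. Of 5445 genes measured on both arrays 552 were higher and 1045 lower, 34.6% of the calls being higher. The median gene stood at -0.04, and after centring on it 577 were higher and 995 lower, 36.7% higher.

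On this array reference genes fell to a median of -1.34 (relative -0.90, percentile 1.1). Of 13 members 11 were lower and none higher. Proliferation and mitosis fell to a median of -0.88 (relative -0.54, percentile 1.57). Of 15 members 7 were lower. The unfolded protein response fell to a median of -1.02 (relative -0.62, percentile 2.03), with 7 of 16 lower, including XBP1 (-1.66 ± 0.22) and the chaperone CALR (-1.64 ± 0.20). Wnt targets fell to a median of -1.22 (relative -0.87, percentile 0.85) with 2 of 4 members lower and 1 higher, and stood 0.63 above matched lists when probes near background were kept. Xenobiotic metabolism rose by 0.43 (relative 0.81, percentile 99.7) and mesenchymal markers by 0.26 (relative 0.63, percentile 98.8); 1 of 6 and 2 of 11 members were higher, and 2 of the mesenchymal markers were lower, among them the integrin ITGA5 (-1.35 ± 0.22). Lists called on another array and not here were heat shock proteins (-0.44, percentile 42.5), oxidative phosphorylation (-0.38, percentile 54.2), ribosomal proteins (-0.88, percentile 6.35), DNA replication (-0.55, percentile 27.8), metallothioneins (-0.78, percentile 25.4), the trithorax group (0.01, percentile 87.5), NRF2 targets (-0.98, percentile 4.55), hypoxia and glycolysis (-0.43, percentile 46.5), developmental factors (-0.22, percentile 86.4), plasma proteins (0.04, percentile 91), complement and coagulation (-0.57, percentile 21.6) and liver-enriched transcription factors (-0.40, percentile 47.9).

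The largest increases were those of GSE1 (6.81 ± 0.27), C5orf15 (6.17 ± 0.35), the zinc finger protein ZNF33A (5.53 ± 0.30) and the calcineurin subunit PPP3CA (5.51 ± 0.25), followed among others by SLC4A5, LHX9, OLFM1, STRA6, SKIL and ALKBH8 down to 5.11 ± 0.28. Of the 115 genes at least 8-fold higher, 83 had another within 5 rows and 2 columns (72.2%, against a mean of 13.03% in random draws), 10 of the 12 largest increases among them, and none lay on raised local background. The largest decreases were those of the ribosomal protein RPL27 (-3.31 ± 0.20), CSE1L (-3.21 ± 0.21), TNFRSF10B (-3.09 ± 0.34), the mitochondrial ribosomal protein MRPL15 (-3.04 ± 0.24) and the histone messenger binding protein SLBP (-3.03 ± 0.29), followed by EMC8, DKK1, KRT83, PARK7, MYL12B, GNG5 and NDUFS8 up to -2.83 ± 0.24. The other measured probe of MYL12B differed upward. Of genes measured on 1 of the 2 arrays only, TRAK2, LINC00879 and SNORA81 were at least 121-, 94.0- and 93.1-fold higher on the array labelled CBX8-shRNA, and C11orf86, H1-2 and DLGAP5 at least 32.5-, 13.9- and 11.5-fold lower. With cyclic loess 961 genes were higher and 691 lower, with normexp and quantile normalization 315 and 427, and with no scaling 276 and 2141. Calls of the unfolded protein response and of mesenchymal markers each ended under 6 alternatives, those of Wnt targets under 4, xenobiotic metabolism and proliferation under 3 each, and reference genes under 2.

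Knockdowns within and between the complexes were set side by side to ask whether subunits of a complex act on the same genes. On the arrays labelled EZH2-shRNA and SUZ12-shRNA together, SNHG6 (3.85 and 3.91), WDR75 (3.93 and 3.72), MCUR1 and FAM20B were among the highest, and SGCE, DMBT1 (-3.36 and -3.20), the metalloprotease ADAM19 (-3.01 and -3.17), AP5Z1 and MCF2L among the lowest. Of these decreases, 4 also pointed downward on the BMI1- and CBX8-labelled arrays, some with wide errors. They were SGCE (-3.67 and -1.26), DMBT1 (-1.83 and -2.72), ADAM19 (-1.42 and -0.88) and AP5Z1 (-2.24 and -4.32). MCF2L differed by 0.80 and -1.16 there. A high value on the shared control array could give such decreases, so they are not particular to the PRC2-labelled pair. On the arrays labelled BMI1-shRNA and CBX8-shRNA together, SUN1 of the nuclear envelope (3.17 and 1.89), the proteoglycan decorin, DCN (1.94 and 1.83), and the growth factor FGF5 (1.63 and 3.99) were higher. The spot of SUN1 on the BMI1-labelled array lay beside other genes at least 8-fold higher there. Lower on both were the nucleotide enzyme IMPDH1 (-3.10 and -2.81), the clathrin adaptor AP2M1 (-2.57 and -2.56), UXT and COX14. Against the control, 2108 genes were higher and 2290 lower on both PRC2-labelled arrays, where independent lists would share 500 and 746; 105 were higher and 563 lower on both PRC1-labelled arrays, against 27.6 and 142. Across complexes, 130 genes were higher on both the EZH2- and CBX8-labelled arrays (84.5 for independent lists) and 122 on both the SUZ12- and CBX8-labelled arrays (81.9), while the EZH2- and SUZ12-labelled arrays shared 42 and 38 increases with the BMI1-labelled array (125 and 116). Shared decreases across complexes lay below independent lists in every pair: 46 for EZH2 and CBX8 (391), 56 for SUZ12 and CBX8 (340), 22 for EZH2 and BMI1 (344) and 19 for SUZ12 and BMI1 (292). Simulated unchanged arrays with a shared control shared on average at most 0.54 genes either way in any pair.

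Across genes, which are not independent replicates, the differences of the EZH2- and SUZ12-labelled arrays correlated at 0.96 (0.55 in simulated unchanged arrays that share the control) with a covariance of 1.40 (simulated 0.03), and those of the BMI1- and CBX8-labelled arrays at 0.69 (simulated 0.40) with a covariance of 0.61 (simulated 0.02). Across complexes the correlations were negative: -0.50 for EZH2 and BMI1, -0.26 for EZH2 and CBX8, -0.47 for SUZ12 and BMI1 and -0.20 for SUZ12 and CBX8, where simulated values were 0.43 to 0.45. Part of any excess may come from the shared control array, which could not be split. Of differences that left the control out, EZH2 minus BMI1 and SUZ12 minus CBX8 had a covariance of 2.84, and EZH2 minus CBX8 and SUZ12 minus BMI1 one of 2.80. That of EZH2 minus SUZ12 with BMI1 minus CBX8, 0.04, equals the gap between these by algebra and is no separate result.

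**Figure D3:**
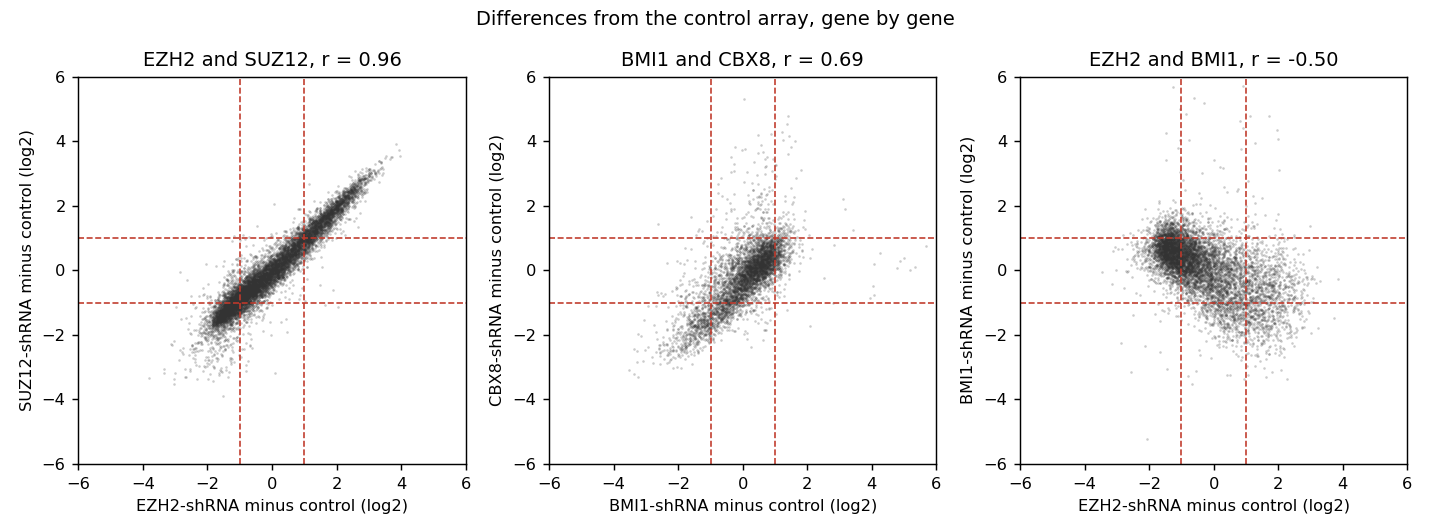
Differences from the control array in log2 units, 1 point per gene measured on the control and both plotted arrays, with dashed lines at -1 and 1; left, EZH2 and SUZ12 (10824 genes); middle, BMI1 and CBX8 (5116 genes, 6 beyond the axes); right, EZH2 and BMI1 (7642 genes, 22 beyond the axes); XIST and genes of the Y chromosome are not drawn. The points follow a rising diagonal on the left (r = 0.96) and in the middle (r = 0.69) and a falling one on the right (r = -0.50).

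Genes that lay at least 1 log2 unit higher on both PRC2-labelled arrays than on both PRC1-labelled arrays numbered 1029, and 1736 lay as far the other way, of 5115 measured on all 4. The other splits of these 4 arrays into pairs gave 0 and 1, and 1 and 0. The widest gaps on the PRC2-labelled side were those of IMPDH1 (4.89), TXNL1 (4.72), the mitochondrial fusion protein MFN2 (4.69), AP2M1 (4.63), C1QBP, TFRC, ACOT13, RAB5IF, EIF3A and TXNDC5. On the PRC1-labelled side they were those of ZNF2 (3.27), the ion channel ASIC4 (3.22), ADGRE1 (3.15), the neuronal kinase DCLK1 (3.13), ADARB2-AS1, MIR23AHG, ZSCAN2, POLR2J2, IL6ST and UTRN. With no scaling the counts were 2849 and 1, and with normexp 640 and 702. Of 5111 genes measured on all 5 arrays, 192 were higher on both PRC2-labelled and lower on both PRC1-labelled arrays and 43 the reverse. Changes shared by all 4 knockdown-labelled arrays were few: the kinetochore protein CENPF (2.04, 1.92, 3.11 and 2.21 in the order EZH2, SUZ12, BMI1, CBX8, with raised local background on the third of these arrays), the phosphatase DUSP1 (1.93, 1.97, 1.55 and 2.12) and HP1BP3, a linker histone relative (2.999, 3.15, 1.38 and 1.28), were higher. The small nuclear RNA RN7SK (-1.17, -1.28, -1.43 and -2.30) and ITGA5 (-1.41, -1.30, -1.16 and -1.35) were lower. All 4 differences use the same control array, so a deviating control value alone can give a change shared by all 4.

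**Figure D4:**
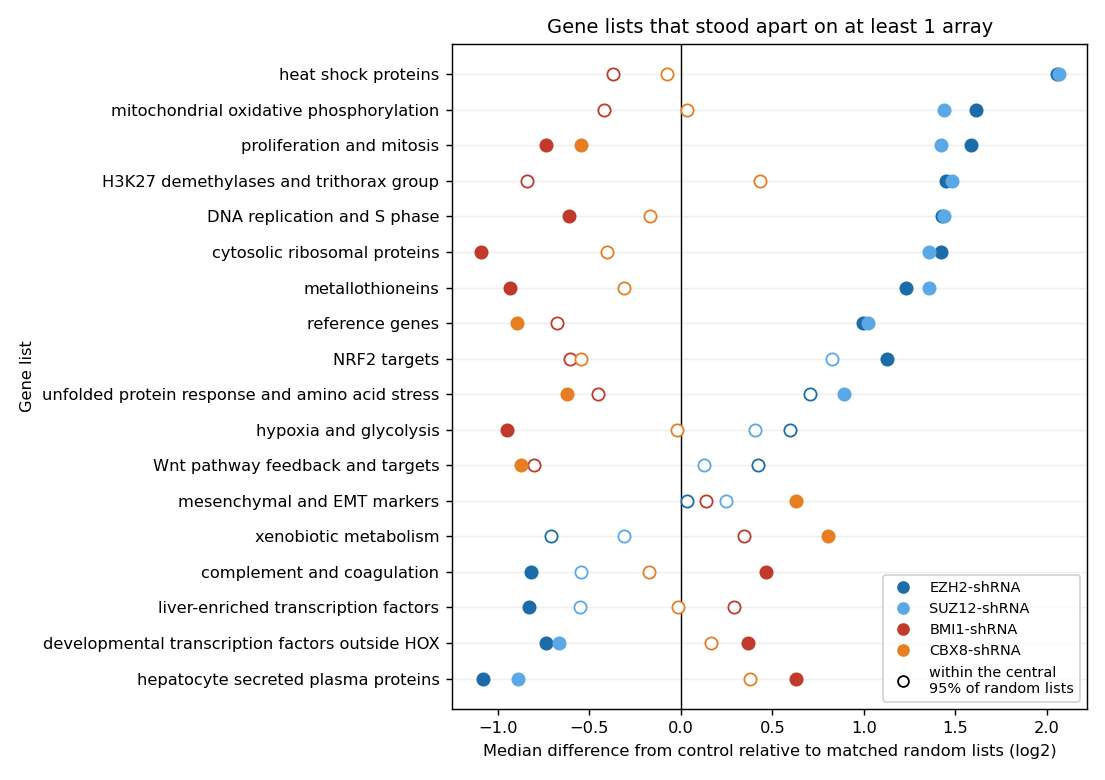
Median difference from the control array of each gene list that stood apart on at least 1 array, in log2 units relative to random lists matched on expression; 1 point per list and array, filled where the list lay outside the central 95% of random lists. Heat shock proteins stood 2.05 and 2.06 above matched lists on the arrays labelled EZH2-shRNA and SUZ12-shRNA, and ribosomal proteins -1.09 and -0.41 from them on those labelled BMI1-shRNA and CBX8-shRNA.

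Of 144 comparisons of a list with its random lists 38 stood apart, where lists of unrelated genes would give about 5%. These lists share members, and all comparisons use the same control array. The EZH2- and SUZ12-labelled arrays were also closely alike. The 144 comparisons are therefore not independent, and the 5% does not measure how many calls go beyond chance. Polycomb subunits and HOX genes, the homeobox clusters that Polycomb represses in many cells, stood apart on none of the 4 arrays. In the order EZH2, SUZ12, BMI1 and CBX8, list medians were -0.21, -0.09, -0.02 and -0.26 for PRC2 subunits (percentiles 41.9 to 58), -0.19, -0.22, -0.04 and -0.21 for PRC1 subunits (percentiles 33.3 to 69.9) and -0.24, -0.21, 0.43 and -0.26 for HOX genes (percentiles 39.7 to 92.7). HOX members went both ways: HOXB9 was 2.64 ± 0.35 and HOXA9 -1.52 ± 0.20 on the array labelled EZH2-shRNA, and HOXA10 was 1.92 ± 0.20 and HOXC6 -1.35 ± 0.21 on that labelled BMI1-shRNA. CDK inhibitors had medians of 0.17, 0.50, 0.06 and -0.23 (percentiles 44.6 to 77.1), where CDKN1C was up by 2.52 ± 0.23 on the array labelled EZH2-shRNA and the Polycomb target CDKN2A differed by -0.06 ± 0.20 on that labelled BMI1-shRNA. Medians were -0.04, -0.27, 0.16 and -0.18 for p53 targets (percentiles 37.8 to 76.4), 0.56, 0.58, -0.27 and -0.21 for apoptosis regulators (percentiles 20 to 93.9), 0.20, 0.04, -0.28 and -0.91 for immediate early genes (percentiles 11.9 to 74.2) and 0.11, 0.23, -0.15 and -0.72 for autophagy and lysosome (percentiles 10.9 to 84.5). Interferon-stimulated genes stood at -0.60, 0.17, -0.27 and -0.84 (percentiles 2.5 to 74.8), with BST2 at -2.56 ± 0.23 on the array labelled CBX8-shRNA, inflammatory cytokines at -0.32, -0.36, -0.14 and -0.18 (percentiles 33.9 to 64.7) and the acute phase response at -0.63, -0.29, 0.27 and -0.25 (percentiles 8.04 to 66.2). Cholesterol synthesis stood at 0.63, 0.72, -0.16 and -0.63 (percentiles 17.3 to 96.7), with NSDHL up by 2.96 ± 0.23 on the array labelled SUZ12-shRNA, and fatty acid synthesis at -0.26, -0.19, 0.48 and -0.01 (percentiles 49.8 to 92.7). Fetal liver genes stood at -0.57, -0.25, 0.46 and -0.26 (percentiles 23.9 to 90.5), with the imprinted RNA H19 up by 2.03 ± 0.21, 1.94 ± 0.21 and 2.16 ± 0.21 on the arrays labelled EZH2-shRNA, SUZ12-shRNA and CBX8-shRNA, and epithelial markers at -0.40, -0.35, -0.29 and -0.36 (percentiles 21.7 to 49.2). For hypoxia and glycolysis the medians on the EZH2- and SUZ12-labelled arrays were 0.33 (percentile 93.7) and 0.21 (percentile 87.4), for Wnt targets 0.36 (percentile 74.1) and 0.08 (percentile 57.8), for mesenchymal markers -0.18 (percentile 53.6) and 0.01 (percentile 74), for xenobiotic metabolism -0.85 (percentile 3.21) and -0.43 (percentile 23.9), and for the unfolded protein response on the EZH2-labelled array 0.47 (percentile 95.3). Markers of other cell types were not called: neuronal genes stood at -1.05, -0.59, 0.42 and 0.10 (percentiles 2.57 to 90.4), immune cell markers at -0.97, -0.91, 0.30 and 0.12 (percentiles 4.22 to 94.9), and stellate, fibroblast and endothelial markers at -0.84, -0.63, 0.55 and 0.06 (percentiles 16.3 to 92.1).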

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

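All tests in this part were chosen after the results were seen. On the array labelled BMI1-shRNA 128 spots had a local background over 2 times the array's median, against 8 on the control array, a signal in a column the comparisons do not use. Of the gene lists, 7 were called on both PRC2-labelled arrays, called the opposite way on at least 1 PRC1-labelled array and lay on that opposite side of matched lists on the other. The difference between complexes was not tested. With spots on raised local background left out, plasma proteins were no longer called on the BMI1-labelled array, which leaves 6. Relative to matched lists, and between the mean of the PRC2-labelled and the mean of the PRC1-labelled arrays, proliferation and mitosis differed by 2.14 log2 units, cytosolic ribosomal proteins by 2.14, metallothioneins by 1.92, DNA replication by 1.82 and reference genes by 1.79, while developmental transcription factors differed by -0.97 and hepatocyte plasma proteins by -1.49.

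The first pattern weighed is this opposition of the arrays by complex. A distortion that depends on spot brightness alone would have been removed by cyclic loess, after which the mean correlation between arrays of different complexes stayed at -0.36 (bootstrap SD 0.0118 over genes), which argues against it as the whole cause. Probes whose signal does not follow the amount of labelled target may contribute, since such probes fall on bright arrays and rise on dim ones once arrays are scaled: across the 5 arrays the slope of unscaled log2 signal on the array's 75th percentile had a median of 0.32 for 115 measured genes of families seldom expressed outside their own tissue (olfactory and taste receptors, keratin-associated proteins, beta defensins, testis antigens), against 1.85 for ribosomal proteins, but these 115 of 605 were kept for being above background on the dim arrays too, which itself favours low slopes, so the value decides nothing. Opposite responses to loss of PRC2 and PRC1 subunits stay open as well, but the order of the 5 arrays along the main axis (85.9% of variance) was their order in brightness for 5 of 5 arrays. Knockdown and array brightness therefore cannot be told apart here, nor can unresponsive probes, because no complex has both a bright and a dim array.

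The second pattern is the size of the largest changes on the BMI1-, CBX8- and SUZ12-labelled arrays, whose genes lie close together on the array surface (83.3%, 72.2% and 41.9% beside another). Since that crowding prompted the question, the other probes around those genes, not picked for their own change, were compared with 1000 shifts of the same positions over the surface. Patches of debris or raised background may account for much of the increases on the BMI1-labelled array, where these probes had a median difference of 1.37 (mean of shifts 0.66, 0.1% as high), and patches of raised signal for those on the CBX8-labelled array, where it was 1.68 (mean 0.56, none as high); raised local background is argued against on the latter, with 0 of 115 genes on it. On the SUZ12-labelled array the median was -0.81 (mean -0.66, 13.5% as low), so patches of low signal cannot be told apart from other causes. Of the decreases of at least 8-fold on the EZH2- and BMI1-labelled arrays, 21.4% and 13.3% lay beside another. Probes around those had medians of -0.65 (82.6% of shifts as low) and 0.90 (81.0% as low). Every difference uses the same control array, and patches on it were not tested apart from those on the knockdown-labelled arrays. Genes outside the patches stay open, and no biological explanation was tested for the positions.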

How the results depend on the processing

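The alternatives with no scaling, centring, other probes for the 75th percentile and no spots on raised background were chosen after seeing the data. No paired analysis was possible because each group held 1 array and no test was run. Of 38 list calls, 35 were kept with quantile normalization, 36 with cyclic loess, 38 with the median in place of the 75th percentile, 30 with normexp, 38 with the series table, 28 with the mean over probes, 20 with genes measured on all 5 arrays (6 lists had no value), 28 with no filter on dim probes, 32 with genes at their bound, 32 with unmatched lists and 37 without raised background; none was called the opposite way. Wnt targets on the CBX8-labelled array reversed with no filter (0.63 relative to matched lists), as did HMGB3 on the EZH2-labelled array with the mean over probes (0.0243). Few probes above background limit the dimmest arrays, with 11803 and 8906 measured probes on the BMI1- and CBX8-labelled arrays.

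Counts below give higher, then lower, in the order EZH2, SUZ12, BMI1, CBX8, where they moved by over 1.5 times. The cause was not tested except where an alternative by construction keeps fewer or more genes or shrinks differences. With normexp they were 596 and 527, 590 and 470, 98 and 358, and 315 and 427. Its offset of 50 exceeded the median processed signal of every array (12.8, 29.7, 29.3, 6.79 and 7.56, control first). Adding it shrinks log2 differences of dim genes by construction. The lower counts therefore do not show dependence on background correction itself. On genes measured on all 5 arrays they were 713 and 1987 for EZH2, 698 higher for SUZ12, 432 higher for BMI1 and 320 higher for CBX8. With no filter they were 3728 and 7533, 3608 and 4283, 6333 and 2070, and 6838 and 3029. At 3-fold they were 1371 and 767, 1258 and 525, 142 and 363, and 304 and 483. Centred on the median difference, 1482 were lower for EZH2, 1271 lower for SUZ12 and 404 higher for BMI1. With no scaling they were 5531 and 51, 5479 and 120, 60 and 3545, and 276 and 2141. For BMI1 the array median gave 394 higher. For CBX8, cyclic loess gave 961 and 691, bounds 1005 higher, and the 75th percentile over probes on all 5 arrays 1023 and 663. SUZ12 on its own array stood at -0.0468 with normexp.

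For EZH2 and SUZ12 together, the correlation was 0.96 with quantile normalization, 0.97 with normexp, 0.95 with the mean over probes, 0.96 on genes on all 5 arrays and 0.90 with no filter, and genes higher and lower on both numbered 502 and 397 with normexp, 3215 and 3708 with no filter, 1155 and 330 at 3-fold, and 636 higher on genes on all 5 arrays. For BMI1 and CBX8 together, the correlation was 0.65 with normexp, 0.65 with no filter and 0.72 without raised background. Genes higher and lower on both of these were 12 and 236 with normexp, 5057 and 1389 with no filter and 8 and 192 at 3-fold, and 266 were higher with cyclic loess, 69 with the array median and 234 with the mean over probes. The mean correlation across complexes was -0.49 on genes on all 5 arrays, -0.18 with no filter, -0.39 without raised background and -0.23 within slide 1. The covariance of the pairing by complex was 2.73 with quantile normalization, 1.12 with normexp, 2.62 with the mean over probes and 3.31 with no filter, and that of EZH2 minus SUZ12 with BMI1 minus CBX8 was 0.0168 with normexp and 0.0852 with no filter. Genes higher on both PRC2-labelled arrays and on both PRC1-labelled arrays numbered 640 and 702 with normexp, 3076 and 7132 with no filter, and 2849 and 1 with no scaling. The other shifts were those of named genes and of list medians. Of the 24 genes named highest or lowest in each comparison, normexp moved 23 for EZH2, 24 for SUZ12, 24 for BMI1 and 24 for CBX8. The shrinkage by its offset enters these moves, and the normexp counts and covariances above. Its share was not separated. For CBX8 the 75th percentile over probes on all 5 arrays moved 24 and cyclic loess 15. Otherwise no setting run on these genes moved more than 10 in any comparison. No scaling, centring, no filter on dim probes and genes on all 5 arrays were not run on them.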

Other observations

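The tests in this part were chosen after the values were seen. Of the plasma proteins that hepatocytes secrete, 13 of 28 list members on the arrays were measured on the control array (46.4%, against 57.8% of all genes). Measured on none of the 5 arrays were 12, among them albumin (ALB), apolipoprotein B (APOB), transferrin (TF), fibrinogen beta (FGB), prothrombin (F2) and plasminogen (PLG). Their processed signals on the control array were 2.30 for ALB, 4.56 for APOB and 3.49 for TF, where negative control spots had a median of 2.40, and alpha-fetoprotein (AFP), a fetal liver protein, gave 2.24. SERPINA1 was measured on all 5 arrays at 1646, 1274, 1439, 1070 and 1557 intensity units in the order control, EZH2, SUZ12, BMI1, CBX8, a range of 1.54-fold, and A1BG at 353, 288, 314, 251 and 326. By contrast the mesenchymal filament VIM gave 4388, 19240, 15724, 2276 and 1890 and the keratin KRT18 49434, 68352, 62994, 17904 and 23350, higher on the bright arrays and lower on the dim ones. Of 17 immune cell markers 15 were well above background on the control array. These genes were chosen after their values were seen.

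The weak liver signal in cells labelled HepG2 is the third pattern weighed. Too little sensitivity stays open: 13 members were measured on the EZH2-labelled array, where random sets with 13 of 28 members measured on the control array had a mean of 17.2 (1.5% of 1000 sets as low), but 14 on the SUZ12-labelled array, where they had 16.0 (18.4% as low). These sets were not matched on the level expected of the transcripts, so they cannot decide the question. Cells other than the labelled line may account for it: 5 of 28 members exceeded the control array's 75th percentile. Of the other 23 only 5 exceeded another array's own 75th percentile on it, KNG1 on raised local background only. All 5 arrays were of cells with the same label, so in other cells these probes would stay dim on each array. The count of 5 therefore says nothing against other cells, and whether the remaining probes can respond is not known. GPC3, a gene of fetal liver and liver cancer, gave 19790, 17511, 20372, 12630 and 23244, a range of 1.84-fold, the keratin KRT7 76167 and CD44 4293 on the control array, while the liver factor HNF4A was measured on the CBX8-labelled array only. No liver sample was on these arrays, so low sensitivity, unresponsive probes and other cells cannot be told apart, and no biological explanation was tested.

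Of 5111 genes measured on all 5 arrays, 438 (8.57%) kept their unscaled signal within 1.5-fold over arrays whose 75th percentiles spanned 5.89-fold, and 416 of these were called lower on both PRC2-labelled arrays after scaling. Scaling takes 1.39 and 1.33 log2 units from the EZH2- and SUZ12-labelled arrays relative to the control array. The count of 416 is therefore largely fixed by construction. For 327 transcripts with 2 measured probes, the contrast of the PRC2-labelled with the PRC1-labelled arrays correlated at 0.56 between the probes, and 21.7% of pairs had opposite signs about the median.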
